A study of Homo sapiens with 12 samples.

How the data were processed

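RNA from 4 untreated ovarian cancer cell lines (IGROV1, SKOV3, TOV112D and TOV21G) was measured on Affymetrix U133 Plus 2.0 arrays, 3 per line. Per the labels' protocols, IGROV1, TOV112D and TOV21G were grown in RPMI medium and SKOV3 in DMEM, total RNA was extracted with Trizol and a column kit, and biotin-labelled cRNA was hybridised. The authors deposited 1 table of log2 expression values for 54675 probe sets on 12 arrays, made with robust multi-array averaging (RMA, affy package) per the submitters' processing notes. The affy version and the annotation used are not given in the sources used here. Deposited values ran from 1.478 to 13.999 with a median of 4.44, and no further transformation was made. RMA subtracts background, quantile-normalizes the arrays and fits probe effects, so an overall difference in RNA content between lines cannot be seen, and values near 2 to 3 lie at the floor of the scale. No detection calls were used, so a fold against a line at the floor depends on that floor and understates or overstates the true ratio by an unknown amount.

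Arrays were assigned to lines by their titles. Genes were named from the platform annotation that pairs probe sets with gene symbols. It listed 42898 probe sets, of which 41097 had 1 gene and 1801 several; 11777 probe sets are unnamed here. After 62 control probe sets and probe sets with several genes were left out, 41091 probe sets measured 19775 genes, and 10523 genes had more than 1 probe set. Each gene was represented by the probe set with the highest mean over all 12 arrays, which was one ending in _x_at (open to cross-hybridisation) for 1140 genes. Symbols were checked against RefSeq genes of assembly GRCh38.p14, used only for names and for which genes neighbour each other. The array files name no genome build, so no coordinates are given. Some genes of the fixed lists are not reported here.

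Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per line over all 12 arrays (8 residual degrees of freedom), contrasts of each line minus the mean of the other 3 and of each pair of lines, moderated by eBayes, with Benjamini-Hochberg adjustment within each contrast. A gene was called at an adjusted p under 0.05 and a difference of at least 1 on the log2 scale (2-fold). It was set apart when it was called in the same direction against each of the other 3 lines. For 26 gene lists, camera was run with a preset correlation of 0.01 in each line, and adjusted over all lists and lines; an estimated correlation and fry were alternatives. The ERBB2 amplicon list and the PI3K and RAS pathway list are given under shortened names. These lists and tests, and all but 1 of the alternatives below, were fixed before the data were examined; some tests of the closing section, and 1 further gene list used there, were chosen later and are named there.

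Named genes followed a rule fixed at the same time. For each line, among genes set apart whose highest line mean reached the median of all values and whose probe set did not end in _x_at, the 10 with the largest positive and the 8 with the largest negative difference from the mean of the other 3 lines were taken. Up to 4 called members per list and line, the 3 largest differences in each direction per pair, and a set of line identity genes were added. SOX2, SALL4 and COL1A2 were named after their values were seen, and so were the levels given for a named gene in a line other than the one it was picked for.

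The tests were checked on simulated data. In each comparison of a line with the other 3, the calls recovered 50 of 50 genes at each simulated log2 change of 1.5, 2, 3 and 4, with 0 false calls among the other genes. At a change of 1.5, 98% were also set apart for the arrays labelled SKOV3 and for TOV21G, and 100% in all other cases. A list of 25 genes raised by 1 on the log2 scale was called in each of the 4 lines, and of the other 100 list and line pairs 0 or 1 was called. The simulated noise was independent between genes, and apart from the added changes the lines did not differ. The simulation therefore cannot show how often camera with the preset correlation wrongly calls a list of correlated genes. In the data the estimated correlation was 0.202 for p53 target genes. The arrays' control probe sets were checked for RNA quality: the 3' minus 5' difference of GAPDH was 0.07 to 0.15 and that of ACTB 0.35 to 0.66 on the log2 scale. No 2 arrays held identical values.

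The alternatives tried were the mean of a gene's probe sets, leaving out probe sets ending in _x_at, leaving out dim genes, centring each array on its median, quantile normalization of the gene values, a trended and robust eBayes prior, the replicate number as a block, leaving out each of the 12 arrays, treating the other 3 lines as 1 group, using only the 6 arrays of a pair, and, added after the data were seen, leaving out the arrays labelled SKOV3. The share of other splits of the arrays that gave as many genes was counted over 100 splits for line contrasts and all 10 for pairs. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.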

Results

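Transcript levels were measured on Affymetrix U133 Plus 2.0 arrays in 4 untreated human ovarian cancer cell lines, IGROV1, SKOV3, TOV112D and TOV21G, with 3 arrays per line and 12 arrays in all. TOV21G was derived from a clear cell carcinoma and TOV112D from an endometrioid carcinoma of the ovary. SKOV3 is widely used as a line with amplified ERBB2. All values are on the log2 scale after robust multi-array averaging, and 19775 genes were tested. Arrays of one line correlated at 0.9972 to 0.9976 over all genes, and arrays of different lines at 0.8892 to 0.9395. The number of arrays limits the precision, and the median standard error of a difference between a line and the mean of the other 3 was 0.077. Nothing in the labels says that the 3 arrays of a line came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

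Genes known to mark these lines were examined first. SMARCA4, the ATPase subunit of the SWI/SNF chromatin remodelling complex, was low in TOV112D at 7.11 ± 0.12 (SD, n = 3), against 10.15 ± 0.04 in IGROV1, 10.39 ± 0.02 in the arrays labelled SKOV3 and 10.32 ± 0.08 in TOV21G. ARID1A, the DNA-binding subunit of the same complex, was lowest in TOV21G at 7.46 ± 0.06, while the other 3 lines measured 9.31 to 10.15. CDKN2A, which encodes the cell cycle inhibitor p16, was highest in TOV112D at 9.62 ± 0.14 and lowest in IGROV1 at 6.63 ± 0.06, by a probe set open to cross-hybridisation. By the same probe set it was at 7.92 ± 0.06 in the arrays labelled SKOV3 and at 8.26 ± 0.13 in TOV21G. CTNNB1, the gene of beta-catenin, stayed between 11.15 and 12.07 in all 4 lines.

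ERBB2 did not follow the label of SKOV3. Its level was 8.14 ± 0.09 (n = 3) in the arrays labelled SKOV3, the lowest of the 4 lines, and 9.01 ± 0.05 in IGROV1, 8.82 ± 0.10 in TOV112D and 8.48 ± 0.04 in TOV21G. The arrays labelled SKOV3 lay 0.63 ± 0.06 (SE) below the mean of the other 3 lines (limma, adjusted p = 7.1e-07), under the 2-fold minimum for a call. GRB7 and MIEN1, neighbours that are amplified together with ERBB2, were not raised either: GRB7 was at 4.44 there and at 6.58, 4.25 and 5.13 in IGROV1, TOV112D and TOV21G, and MIEN1 at 8.41 against 9.44, 9.79 and 9.85. The neighbours STARD3 and PGAP3 differed less from the mean of the other 3 lines, by -0.12 and -0.09. Of 17 measured ERBB2 amplicon genes, 1 was called higher in these arrays and 1 lower. The higher one was CDK12, whose difference with the mean of all probe sets was 0.55, under the minimum for a call. Because of these values the group is called "the arrays labelled SKOV3" throughout, and each direction given for it holds for those arrays.

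**Figure D1:**
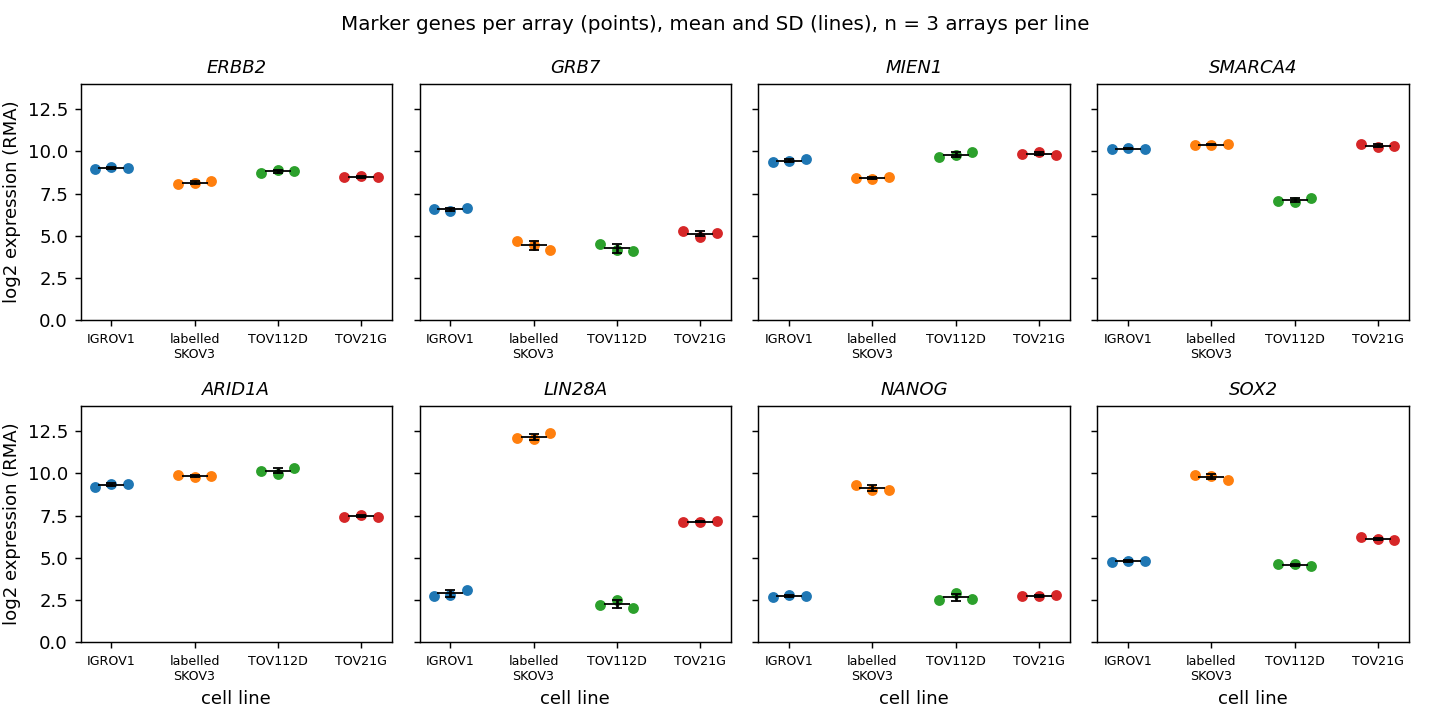
Log2 expression (vertical axis) of 8 marker genes on each of the 12 arrays, by cell line (horizontal axis); points are arrays, and lines are the mean and SD of 3 arrays. ERBB2 was lowest in the arrays labelled SKOV3 (8.14), SMARCA4 was low in TOV112D (7.11), ARID1A was low in TOV21G (7.46), and LIN28A, NANOG and SOX2 were highest in the arrays labelled SKOV3 (12.16, 9.12 and 9.79).

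IGROV1 was compared with the mean of the other 3 lines to describe its own expression profile. Epithelial junction and keratin genes were higher as a group in IGROV1, although single members such as KRT8, KRT18 and CD24 were as high or higher in another line. KRT19, a keratin of simple epithelia, was 8.57 ± 0.12 (SE) higher on the log2 scale, with a mean of 11.84 against 2.76 to 4.05 elsewhere (limma, adjusted p = 5.1e-14, n = 3 arrays per line). CDH1, the gene of E-cadherin, was 7.48 ± 0.23 higher (adjusted p = 3.9e-11). In the opposite direction, CCN2, a matrix protein induced by YAP and TGF-beta, was at 2.80 in IGROV1 and at 9.06 to 11.08 in the others. TWIST1, a transcription factor of mesenchymal transition, was at 2.51 against 7.12 to 12.08.

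In all, 1424 genes were higher and 1404 lower in IGROV1, and 884 were set apart from each of the other 3 lines in the same direction, 518 of them higher and 366 lower. After KRT19 and CDH1, the genes that stood out most as higher were DCAF12L1 (by 7.44), the transport protein gene MAL2 (7.43), the guanine deaminase gene GDA (6.64), ZBED2 (6.52), the filaggrin gene FLG (6.49), the neuropeptide gene NMU (6.47), HSPB3 (6.41) and the inhibin subunit gene INHBB (6.37). MAL2 and GDA were also high in TOV21G, at 9.86 and 10.37. The lowest genes after CCN2 were ARMCX6, ARMCX3 and TCEAL8, 3 genes of the X chromosome at 3.51, 2.38 and 2.52 in IGROV1 and at 8.55 or above in every other line. GASK1B, the palmitoyltransferase gene ZDHHC2 and the ephrin gene EFNB2 were lower by 6.46, 6.41 and 6.40 on the log2 scale. The mismatch repair gene MSH6 was at 6.76 in IGROV1 against 10.13 to 11.09 in the others, and EBP, a sterol isomerase of cholesterol synthesis, was at 4.17 against 9.28 to 9.84.

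Among the gene lists fixed in advance, epithelial junction and keratin genes rose together in IGROV1. Of 26 measured members, 19 were higher and 0 lower, with a mean difference of 2.87 (camera, adjusted p = 8.4e-11). EPCAM stood at 12.17 against 7.79 or less, and KRT7 at 10.04 against 6.06 or less. Interferon-stimulated genes were also higher as a group, with 13 of 27 members higher and 1 lower (adjusted p = 7e-05). LGALS3BP and IFIT3 were higher by 4.34 and 3.12, while HERC5 was lower by 4.36. Stromal fibroblast and smooth muscle markers were lower, with 14 of 21 members down and 0 up (adjusted p = 5.9e-08). COL5A2, POSTN and THY1 measured 3.81, 2.53 and 4.25 in IGROV1, close to their levels in TOV21G. Targets of Wnt and beta-catenin were lower in 10 of 25 cases and higher in 1 (adjusted p = 9.4e-05), with AXIN2 at 4.74 and LEF1 at 3.03 among the lower ones.

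Other groups passed the test in IGROV1 only with the preset correlation. Mesenchymal transition genes, with 12 of 23 lower and 2 higher, had adjusted p = 0.0017, and 0.1 as the adjusted p with an estimated correlation. NRF2 target genes, with 7 of 24 higher and 0 lower, had adjusted p = 0.00062 and 0.12 with the estimated correlation. ME1 was higher by 2.77 and AKR1B10 by 2.04. MHC class I presentation genes had 4 of 16 members higher and 1 lower (adjusted p = 0.0053, and 0.18 with the estimated correlation), and HLA-C was higher by 1.87. Without the arrays labelled SKOV3 the mean went from 0.72 to 0.28 (adjusted p = 0.36), so this call rests on those arrays. Target genes of p53 had 6 of 25 higher and 2 lower (adjusted p = 0.034, and 0.5 with the estimated correlation), with PHLDA3 and FAS higher by 2.22 and 1.60. This call was also lost without probe sets ending in _x_at (adjusted p = 0.053), without dim genes (0.11), under quantile normalization (0.074) and in 1 fit with an array left out (0.052). Cholesterol synthesis genes had a median of 0.54 and a mean of 0.06 over 18 members, 0 of them higher and 2 lower (adjusted p = 0.036, and 0.39 with the estimated correlation). It was also lost without probe sets ending in _x_at (adjusted p = 0.088), without dim genes (0.11) and under quantile normalization (0.074). Markers of Mullerian and serous carcinoma did not pass as a group (7 of 22 higher, 2 lower, adjusted p = 0.13, and 0.019 without the arrays labelled SKOV3), although SLPI, SOX17, MECOM and MSLN were higher by 6.13, 6.07, 4.88 and 3.15. Neural and stem cell genes did not pass in IGROV1 (4 of 24 higher, 9 lower, adjusted p = 0.066) but did as lower with the mean of all probe sets (0.021), without probe sets ending in _x_at (0.049) and with centred arrays (0.042). PAX8, the Mullerian lineage factor, was at 10.26 in IGROV1 and 10.04 in TOV21G, and at 7.12 and 6.96 in the arrays labelled SKOV3 and in TOV112D.

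The arrays labelled SKOV3 were compared with the mean of the other 3 lines in the same way. GREM1, TRIM71 and LIN28A were among the genes highest in these arrays, and FABP5 and GPX1 were the lowest. LIN28A, an RNA-binding protein gene of early development, was at 12.16 ± 0.19 (SD, n = 3) and exceeded the other lines by 8.06 ± 0.11 (SE, limma, adjusted p = 3.9e-14). TRIM71, another regulator of early embryonic cells, was higher by 8.58 ± 0.12, and GREM1, a secreted inhibitor of bone morphogenetic proteins, by 8.92 ± 0.09 (adjusted p = 4.1e-15). FABP5, a fatty acid binding protein gene, was at 2.53 there and at 10.93 to 12.02 in the other lines. The glutathione peroxidase gene GPX1 was at 3.48 against 11.10 to 11.92.

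A total of 1291 genes were higher and 1583 lower in the arrays labelled SKOV3, and 1062 were set apart from each of the other 3 lines, 594 higher and 468 lower. With each array centred on its median the excess of lower genes was gone, with 1400 higher and 1402 lower. Under quantile normalization of the gene values part of the excess remained, with 1360 higher and 1477 lower. The further leading genes were TCEAL7 (higher by 8.20), the phosphatase gene PTPRZ1 (7.87), the adhesion receptor gene ADGRL4 (7.27), ARMCX2 (7.22), the histamine methyltransferase gene HNMT (7.14), the NADPH oxidase gene NOX4 (7.10) and the matrix protein gene SPARC (6.92). LIN28A was also measured at 7.15 in TOV21G, and ARMCX2 at 8.13 in TOV112D. Among the lowest was ALDH1A1, a retinaldehyde dehydrogenase gene, at 2.53 against 7.51 in IGROV1 to 12.30 in TOV112D. The actin-severing protein gene SCIN was at 2.18 against 5.15 in TOV112D to 11.39 in TOV21G. HTATIP2, NFIB, BICC1 and GPRC5A lay 6.74, 6.72, 6.68 and 6.57 below the mean of the others. These arrays differ from the rest in culture medium as well, since SKOV3 alone was grown in DMEM per the labels' protocols.

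HOX cluster genes fell together in the arrays labelled SKOV3, with 14 of 28 measured members lower and 0 higher (camera, adjusted p = 1.1e-07). HOXB7 was at 3.28 against 8.78 to 9.47, and HOXB6 at 3.33 against 4.74 to 9.27. MHC class I presentation genes were lower in 11 of 16 cases and higher in 0 (adjusted p = 9e-06, and 0.048 with the estimated correlation). PSMB9 was lower by 3.97, TAP1 by 2.90 and ERAP2 by 3.26. Cytokine and chemokine genes under NF-kappaB were lower in 12 of 22 cases and higher in 1 (adjusted p = 0.001), with CXCL1 at 4.10 and IL18 at 3.21. Their mean difference was -1.36, against 0.68 in IGROV1, -2.11 in TOV112D and 2.79 in TOV21G. The high TOV21G values therefore add to this call. Stromal fibroblast and smooth muscle markers were higher in 11 of 21 cases and lower in 4 (adjusted p = 0.0013, and 0.034 with the estimated correlation). TAGLN was higher by 5.41, COL5A1 by 5.21 and COL1A1 by 4.39.

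Another 5 groups were called only with the preset correlation in these arrays. Mesenchymal transition genes were higher in 11 of 23 cases and lower in 2 (adjusted p = 0.00033, and 0.069 with the estimated correlation), including TGFBI by 5.77 and the N-cadherin gene CDH2 by 4.59. Epithelial junction and keratin genes were lower in 12 of 26 cases and higher in 3 (adjusted p = 0.0026, and 0.1 with the estimated correlation). EPCAM was at 3.41 and CDH1 at 2.95, while KRT8 and KRT18 were at 11.75 and 12.62. Interferon-stimulated genes were lower in 10 of 27 cases and higher in 3 (adjusted p = 0.0053, and 0.12 with the estimated correlation), with IFIH1 lower by 4.42 and IFI6 by 2.58. Drug transporter and platinum response genes were lower in 9 of 26 cases and higher in 1 (adjusted p = 0.03, and 0.23 with the estimated correlation), and that 1 was the efflux transporter gene ABCG2, higher by 4.52. Without dim genes this call was lost (adjusted p = 0.073). PI3K and RAS pathway genes were higher in 5 of 20 cases and lower in 2 (adjusted p = 0.03, and 0.19 with the estimated correlation), with PHLDA1 and SPRY4 higher by 2.89 and 2.08; without dim genes this call was lost as well (adjusted p = 0.054). Neural and stem cell genes did not pass as a group (10 of 24 higher, 3 lower, adjusted p = 0.053), with a median of 0.04 and a mean of 1.35. The list did pass without probe sets ending in _x_at and without dim genes (adjusted p = 0.038 in each) and in 4 of the fits with an array left out (0.037 to 0.046). NANOG and LIN28B were higher by 6.39 and 6.35, and SOX2 and SALL4, picked from the list after their values were seen, were at 9.79 and 9.46 against 6.13 or less and 5.62 or less. Endothelial markers had 5 of 14 members higher and 1 lower (adjusted p = 0.079, and 0.0041 with the mean of all probe sets), with KDR at 7.41 and TIE1 at 5.83. The antigen gene PRAME was lower by 5.10.

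TOV112D was likewise set against the mean of the other 3 lines. The hormone gene GCG and the matrix genes COL3A1 and LUM were its highest genes against the other lines, and SPP1 and CD44 its lowest. GCG, which encodes glucagon, was at 13.49 ± 0.09 (SD, n = 3) against 2.40 or less, a difference of 11.13 ± 0.08 (SE, limma, adjusted p = 1.9e-16). The collagen gene COL3A1 was higher by 10.52 ± 0.08 and the proteoglycan gene LUM by 9.41 ± 0.06. SPP1, the gene of osteopontin, was at 2.87 against 12.73 to 13.60 (lower by 10.18, adjusted p = 2.6e-17), and the hyaluronan receptor gene CD44 was at 2.21 against 10.36 to 11.06.

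The comparison called 1391 genes higher and 1510 lower in TOV112D, and 1064 genes were set apart from each of the other 3 lines, 594 higher and 470 lower. Other genes among the 10 highest were the stromelysin gene MMP10 (by 8.61), the noncoding RNA gene DNM3OS (8.40), the claudin gene CLDN11 (8.34), RGCC (8.10), the prolactin gene PRL (7.99), MTUS1 (7.22) and the aggrecanase gene ADAMTS5 (7.17). Among the 8 lowest were RBPMS, ARHGAP29, ANXA3, LRATD2 and PHLDB2, each below 3 in TOV112D and at 9.70 or above in the other lines. S100A4, a calcium-binding protein gene, was at 4.88 against 11.25 to 13.12.

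Epithelial junction and keratin genes were lower in TOV112D in 17 of 26 cases and higher in 0 (camera, adjusted p = 9.5e-09). KRT18 was at 5.01 against 11.37 or above, and the desmoplakin gene DSP at 2.82 against 7.92 or above. Targets of Wnt and beta-catenin were higher in 11 of 25 cases and lower in 1 (adjusted p = 8.6e-05). AXIN2 was at 11.96 and APCDD1 at 9.52, higher by 5.50 and 5.23, and DKK1 was at 11.90, close to its 11.95 in TOV21G; the 1 lower member was CD44. HOX cluster genes were higher in 14 of 28 cases and lower in 1 (adjusted p = 0.00032, and 0.037 with the estimated correlation). HOXC6, HOXB3, HOXC9 and HOXC10 were higher by 6.46, 5.85, 4.46 and 4.40. NF-kappaB cytokine and chemokine genes were lower in 15 of 22 cases and higher in 0 (adjusted p = 1.2e-05), with CXCL3 at 3.32 and IL6 at 4.24. Clear cell carcinoma markers were lower in 11 of 18 cases and higher in 1 (adjusted p = 0.00014), led by SPP1.

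With the estimated correlation 4 further calls in TOV112D were lost. Target genes of p53 were lower in 13 of 25 cases and higher in 2 (adjusted p = 1.1e-07, and 0.12 with the estimated correlation). FAS was at 5.49 against 7.58 to 11.06, and PHLDA3 at 4.90 against 6.74 to 8.87. Mullerian and serous carcinoma markers were lower in 9 of 22 cases (adjusted p = 0.0021, and 0.13 with the estimated correlation), with MECOM at 2.74 and WT1 at 3.29. Drug transporter and platinum response genes were lower in 8 of 26 cases and higher in 1 (adjusted p = 0.0029, and 0.13 with the estimated correlation), and this call was also lost without probe sets ending in _x_at (adjusted p = 0.15). PI3K and RAS pathway genes were lower in 6 of 20 cases (adjusted p = 0.034, and 0.2 with the estimated correlation), with the growth factor receptor gene EGFR lower by 2.83 and DUSP4 by 3.07. With the mean of all probe sets the EGFR difference was -0.93, under the minimum for a call, and the list call was lost (adjusted p = 0.073), as it was without dim genes (0.057) and without the arrays labelled SKOV3 (0.28). Stromal markers did not pass as a group (8 of 21 higher, 3 lower, adjusted p = 0.093, and 3e-04 without the arrays labelled SKOV3), although COL3A1 and LUM belong to it and DCN was higher by 5.01; the collagen gene COL1A2 was at 3.73, and COL1A1 and COL5A1 were not called. Interferon-stimulated genes went both ways, with 6 higher and 7 lower of 27 (adjusted p = 0.19, and 0.03 as lower without the arrays labelled SKOV3): the RNA sensor gene IFIH1 was higher by 6.71 and BST2 lower by 5.12. Within the SWI/SNF complex, SMARCA4 was lower by 3.18 ± 0.06 (adjusted p = 2.5e-13). SMARCA2, its paralogue, measured 2.65 in TOV112D and 6.73 in TOV21G by a probe set ending in _x_at. Without such probe sets its difference was 0.02 in TOV112D and 0.13 in TOV21G, a call in neither. The probe set used in that setting stayed below the median of all values in every line. The 2 other probe sets that reached this median went the same way as the main one in both lines. With the mean of all probe sets the TOV112D difference was -0.52, under the minimum for a call. The antigen gene PRAME was higher by 3.71 and the stem cell marker gene ALDH1A1 by 6.05.

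TOV21G was the last line set against the mean of the other 3. NF-kappaB cytokine and chemokine genes were higher as a group in TOV21G, and SRGN and EREG led the single genes. SRGN, a proteoglycan gene of secretory granules, was at 12.78 ± 0.07 (SD, n = 3) against 5.42 or less, higher by 9.20 ± 0.15 (SE, limma, adjusted p = 2.9e-13). EREG, which encodes an EGF receptor ligand, was higher by 8.63 ± 0.11. The chemokine gene CXCL5 was at 11.81 and CXCL1 at 11.84, higher by 7.45 and 6.36, and IL6 was at 11.05, higher by 5.85 (adjusted p = 2.9e-13). BCAT1, an enzyme gene of branched-chain amino acid catabolism, was at 2.70 against 5.77 to 12.50.

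In TOV21G 1403 genes were higher and 1018 lower, and 658 genes were set apart from each of the other 3 lines, 469 higher and 189 lower. Next among the highest were DNER (by 8.42), the cartilage matrix gene COMP (8.13), the fibrinogen gene FGB (7.64), the reelin gene RELN (7.26), the nephronectin gene NPNT (6.99), the pyruvate dehydrogenase kinase gene PDK4 (6.90), SPOCK1 (6.62) and APBB1IP (6.62). Among the lowest after BCAT1 were the histone gene H2BC12 at 3.66 against 9.33 or above, and SLC25A46, EPM2AIP1, ZNF140 and CHCHD5, each below 3 in TOV21G and at 7.80 or above in the others. The neurotensin gene NTS was at 2.52 against 5.35 in IGROV1 to 12.10 in the arrays labelled SKOV3, and SPAG16 was lower by 5.21. The median of all genes was higher in TOV21G than in the other lines, and centring each array on its median dropped the TOV21G difference of every gene by 0.13. After centring 1197 genes were higher and 1257 lower in TOV21G. Under quantile normalization of the gene values 1343 were higher and 1096 lower. The excess of higher genes was thus lost in the first setting and smaller in the second, so its size depends on the scaling.

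NF-kappaB cytokine and chemokine genes rose as a group in TOV21G, with 16 of 22 members higher and 0 lower and a mean difference of 2.79 (camera, adjusted p = 1.1e-07). Clear cell carcinoma markers were higher in 10 of 18 cases and lower in 2 (adjusted p = 0.0017, and 0.037 with the estimated correlation). TFPI2, a protease inhibitor gene, was higher by 4.30, while DPP4 was lower by 3.55. Stromal fibroblast and smooth muscle markers were lower in 12 of 21 cases and higher in 2 (adjusted p = 1.2e-05), with COL5A2 at 3.79 and POSTN at 2.49.

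In TOV21G 5 calls held only with the preset correlation. Target genes of p53 were higher in 11 of 25 cases and lower in 0 (adjusted p = 1.2e-06, and 0.14 with the estimated correlation). CDKN1A, the gene of the cell cycle inhibitor p21, was at 11.59 against 6.50 to 9.39, and FAS at 11.06. Drug transporter and platinum response genes were higher in 11 of 26 cases and lower in 1 (adjusted p = 0.00061, and 0.1 with the estimated correlation). The metallothionein genes MT1E and MT1F were each higher by 2.43, and this call was also lost without probe sets ending in _x_at (adjusted p = 0.092). MHC class I presentation genes were higher in 5 of 16 cases and lower in 0 (adjusted p = 0.00084, and 0.12 with the estimated correlation), with PSMB8 higher by 4.44 and TAP1 by 2.15. Without the arrays labelled SKOV3 the mean went from 0.94 to 0.53 (adjusted p = 0.23), so this call also rests on those arrays. Neural and stem cell genes were lower in 10 of 24 cases and higher in 2 (adjusted p = 0.0064, and 0.12 with the estimated correlation), with PROM1 lower by 4.76; this call was also lost without dim genes (adjusted p = 0.14) and without the arrays labelled SKOV3 (0.084). Proliferation genes shifted by a mean of -0.20 with 0 of 36 members called (adjusted p = 0.018, 0.29 with the estimated correlation and 0.051 without dim genes). In the SWI/SNF complex, ARID1A was lower by 2.31 ± 0.07 (adjusted p = 3.2e-11) and BRD7 by 1.25. The antioxidant gene NQO1 was higher by 2.28 and the cystine transporter gene SLC7A11 lower by 3.72.

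**Figure D2:**
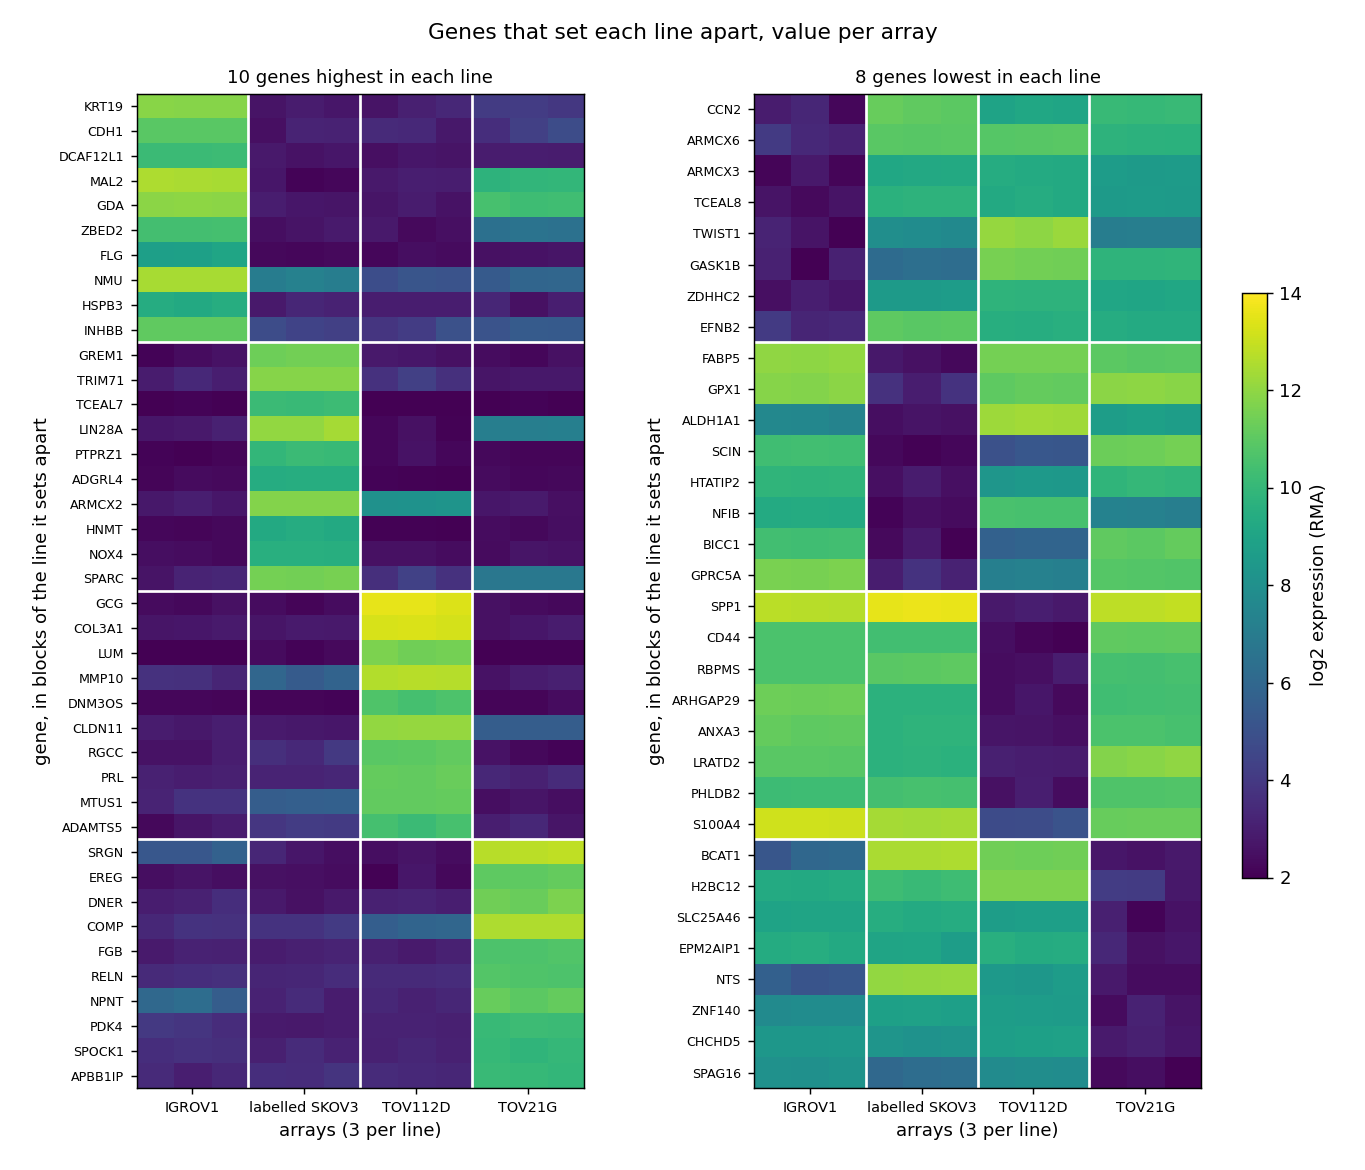
Log2 expression (colour) on each of the 12 arrays (columns, 3 per line) of the 10 highest (left) and 8 lowest (right) genes that set each line apart from the other 3 (rows, in blocks by line). In TOV112D, GCG reached 13.49 and SPP1 was at 2.87; in the arrays labelled SKOV3, LIN28A reached 12.16 and FABP5 was at 2.53.

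Ribosomal protein genes, MHC class II genes, cancer-testis antigen genes, endothelial markers, leukocyte and erythroid markers, ERBB2 amplicon genes, DNA mismatch repair genes, SWI/SNF genes, and hypoxia and glycolysis genes were not called as groups in any line by the planned test. Leukocyte and erythroid markers had at most 2 of 14 members higher in a line. Of 16 measured cancer-testis antigen genes, 14 stayed below the median of all values in every line. Hypoxia and glycolysis genes moved singly: the glucose transporter gene SLC2A3 was at 12.80 in the arrays labelled SKOV3 and at 3.33 in IGROV1, and SLC2A1 was lower in TOV112D by 3.96. With an estimated correlation 16 camera calls held: epithelial genes in IGROV1 and TOV112D, stromal markers in IGROV1, the arrays labelled SKOV3 and TOV21G, clear cell markers and NF-kappaB cytokine genes in TOV112D and TOV21G, and the latter also in the arrays labelled SKOV3. The others were Wnt targets in IGROV1 and TOV112D, HOX genes in the arrays labelled SKOV3 and TOV112D, interferon-stimulated genes in IGROV1 and MHC class I genes in the arrays labelled SKOV3. Median, mean and camera direction differed in sign only in lists without a call. These were ERBB2 amplicon, HOX, hypoxia, and drug transporter genes in IGROV1, and leukocyte, cancer-testis, and neural and stem cell genes in TOV112D. In TOV21G these were NRF2 targets, and in the arrays labelled SKOV3 they were Mullerian, Wnt, ERBB2 amplicon, SWI/SNF, MHC class II, cancer-testis, proliferation and hypoxia genes. Counts of called members adjusted over the list alone equalled those adjusted over all genes for each list and line.

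**Figure D3:**
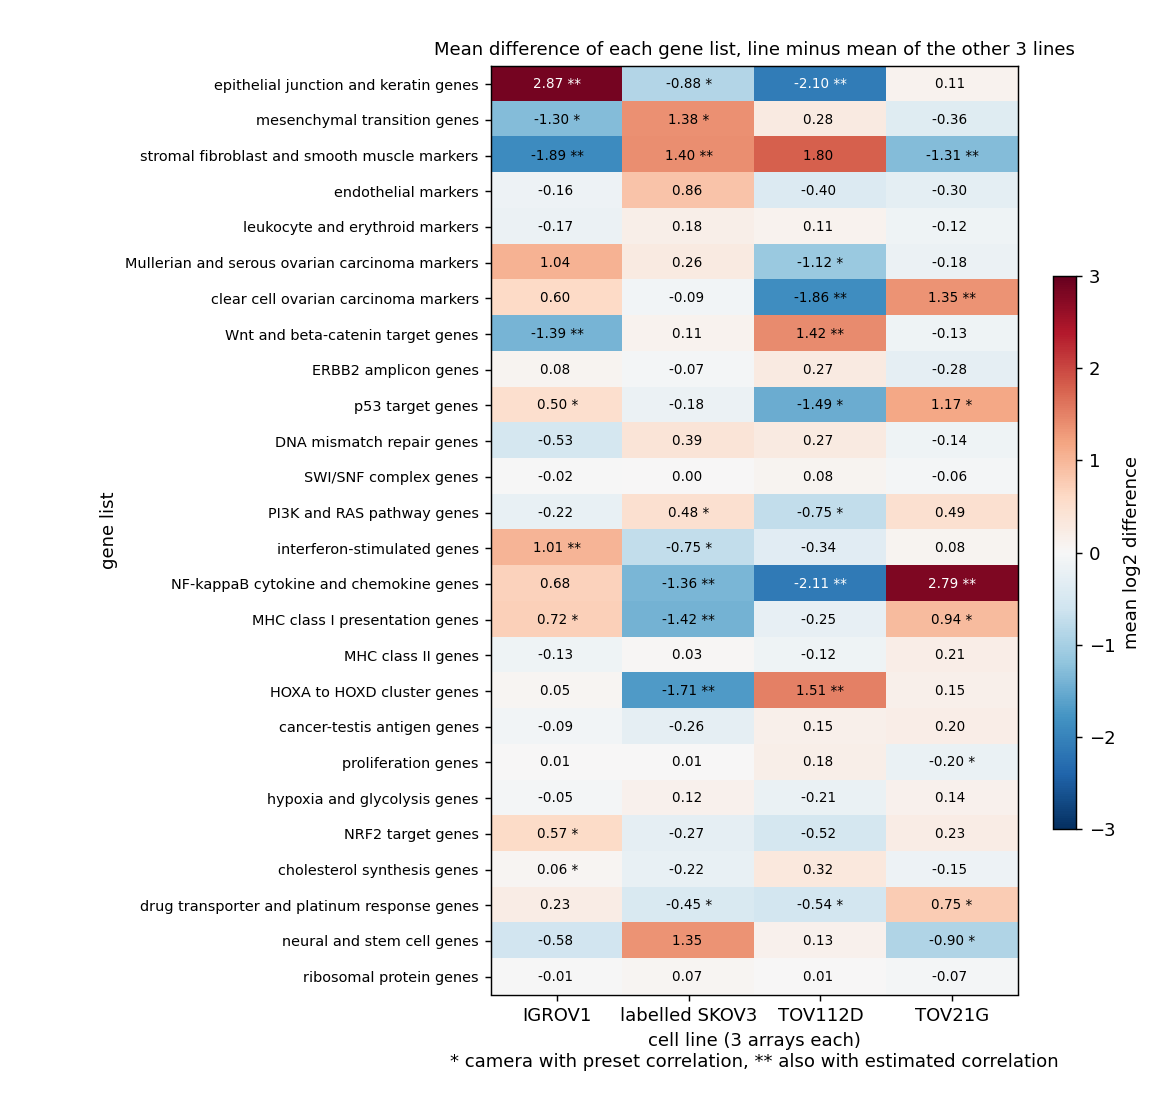
Mean log2 difference (colour and number) of each of 26 gene lists (rows) in each line minus the mean of the other 3 lines (columns, 3 arrays each); 1 star marks a camera call with the preset correlation and a pair of stars a call that also held with an estimated correlation. Epithelial genes had a mean of 2.87 in IGROV1 and -2.10 in TOV112D, and NF-kappaB cytokine genes 2.79 in TOV21G and -2.11 in TOV112D.

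The 6 pairs of lines were compared to give the distance between them. IGROV1 and TOV21G were closest, with 2487 genes different, 1156 higher in IGROV1 and 1331 higher in TOV21G. KRT19, DCAF12L1 and the galanin gene GAL were higher in IGROV1 by 7.80, 7.27 and 6.98, and the Wnt inhibitor gene DKK1, COMP and EREG were higher in TOV21G, with differences of -9.19, -8.93 and -8.56 for IGROV1 minus TOV21G (limma, adjusted p from 3.2e-14 to 6.6e-11). Correlations between arrays of these lines were 0.9383 to 0.9395, above those of any other pair.

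IGROV1 and the arrays labelled SKOV3 differed in 3714 genes, the most of any pair, 2008 of them higher in IGROV1. By correlation IGROV1 and TOV112D lay furthest apart, at a mean of 0.89 against 0.898 for this pair. MAL2, FABP5 and GDA were higher in IGROV1 by 10.13, 9.49 and 9.14. SLC2A3, LIN28A and GREM1 were higher in the arrays labelled SKOV3, with differences of -9.46, -9.27 and -9.03 for IGROV1 minus SKOV3. Between IGROV1 and TOV112D, 3560 genes differed, 1798 of them higher in IGROV1. SPP1, MAL2 and GDA led in IGROV1, by 9.86, 9.55 and 9.20, and GCG, COL3A1 and TWIST1 led in TOV112D, with -11.12, -10.52 and -9.56 for IGROV1 minus TOV112D.

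The arrays labelled SKOV3 and TOV112D differed in 3185 genes, of which 1505 were higher in the former. SPP1, LIN28A and PRTG were higher in the arrays labelled SKOV3 by 10.73, 9.90 and 9.04. GCG, COL3A1 and ALDH1A1 were higher in TOV112D, with -11.17, -10.50 and -9.77 for SKOV3 minus TOV112D. Against TOV21G, the arrays labelled SKOV3 differed in 3448 genes, 1507 higher and 1941 lower. BCAT1, NTS and ARMCX2 were higher by 9.80, 9.58 and 9.08, and SRGN, SCIN and DNER were lower, at -9.95, -9.21 and -8.71. TOV112D and TOV21G differed in 3361 genes, 1550 of them higher in TOV112D. GCG, COL3A1 and MMP10 were higher in TOV112D by 11.09, 10.53 and 9.79, and SRGN, SPP1 and the integrin gene ITGB8 were higher in TOV21G, with -10.29, -9.97 and -9.06 for TOV112D minus TOV21G. Each pairwise difference named here had an adjusted p of 6.6e-11 or less (limma, 3 arrays per line).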

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

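Every count stayed within 1.5 times its value under probe set means, without _x_at probe sets, without dim genes, under median centring, quantile normalization and a trended robust prior, and, for pairs, with only the 6 arrays of the lines compared. Treating the other 3 lines as 1 group lowered the higher and lower counts to 803 and 585 in IGROV1, 817 and 846 in the arrays labelled SKOV3, 916 and 729 in TOV112D, and 677 and 339 in TOV21G, because differences among the other lines then count as spread. Without the arrays labelled SKOV3, a setting added after the data were seen, 2030 genes were set apart in TOV112D and 1003 in TOV21G, because only 2 lines are then left to differ from, and 2263 of 2828 calls in IGROV1, 2521 of 2901 in TOV112D and 1922 of 2421 in TOV21G stayed calls in the same direction, 0, 2 and 2 became calls in the opposite one, and the rest were no longer calls. There 7 list shifts became calls and 4 were lost. In that setting the difference turned for ABCG2 in IGROV1 (0.02), KDR in TOV112D (0.21) and in TOV21G (0.03), and TIE1 (0.05) and SLC2A3 (0.15) in TOV21G. The mean of all probe sets turned PECAM1 in IGROV1 (-0.49), and leaving out _x_at probe sets turned CXCL2 in IGROV1 (-0.42) and SMARCA2 in TOV112D (0.02); the cause was not tested. With fry, which does not compare a list with other genes, 50 more list shifts were called in the camera direction and 8 more against it: ERBB2 amplicon (0.08), HOX (0.05) and hypoxia genes (-0.05) in IGROV1, Mullerian markers (0.26), cancer-testis (-0.26) and hypoxia genes (0.12) in the arrays labelled SKOV3, and cancer-testis (0.15) and neural and stem cell genes (0.13) in TOV112D. An estimated correlation ended 19 camera calls. Centring made ribosomal protein genes a call in the arrays labelled SKOV3 (0.15) and in TOV21G (-0.21), neural and stem cell genes in IGROV1 (-0.52) and ERBB2 amplicon genes in TOV112D (0.27; also without IGROV1 replicate 3 and without TOV21G replicate 2), and evened the balance of TOV21G from 58% to 48.8% higher. Leaving out dim genes made NF-kappaB genes a call in IGROV1 (1.02), and the mean of all probe sets proliferation genes in TOV112D (0.19). Of the named gene calls, the mean of all probe sets ended 45 without turning them, and leaving out _x_at probe sets 10. Leaving out each array in turn gave higher counts of 1408 to 1453 in IGROV1, 1275 to 1300 in the arrays labelled SKOV3, 1366 to 1415 in TOV112D and 1389 to 1437 in TOV21G. The lower counts were 1385 to 1413, 1558 to 1635, 1499 to 1535 and 1011 to 1024, and 875 to 890, 1056 to 1078, 1059 to 1084 and 649 to 667 genes were set apart. Pairs gave 3693 to 3751 (IGROV1 and SKOV3), 3554 to 3580 (IGROV1 and TOV112D), 2474 to 2494 (IGROV1 and TOV21G), 3180 to 3217 (SKOV3 and TOV112D), 3438 to 3492 (SKOV3 and TOV21G) and 3341 to 3388 (TOV112D and TOV21G). The replicate number as a block left each line count unchanged and moved a pair count by at most 1 (3448 to 3449 for SKOV3 and TOV21G). Deviations from the line mean of each gene were then correlated between arrays of different lines. Their mean correlation was 0.02 for arrays of the same replicate number and -0.01 for arrays of different numbers. By these deviations 5 of 12 arrays matched best to an array of their own number, a hint that the numbers do not pair samples. Of 100 splits of the arrays, the number that gave at least the real count, the real split included, was 1 for each higher count and for each lower count but that of TOV21G (2), each a share under 0.05. The highest other was 1110, 850, 1172 and 1133 for higher, against the real 1424, 1291, 1391 and 1403. For lower it was 989, 891, 982 and 1103, against the real 1404, 1583, 1510 and 1018. Without groups of 3 arrays of 1 line it was 349, 467, 321 and 447 for higher, and 221, 758, 355 and 724 for lower. A group that mixes lines carries their differences as spread and could hardly reach the real count. These shares therefore show only that arrays of 1 line resemble each other, and do not exclude chance. For genes set apart, 4 splits reached the real count in IGROV1 (real 884, highest other 1005) and 1 in the arrays labelled SKOV3 (1062, 998). In TOV112D it was 1 (1064, 1021) and in TOV21G 5 (658, 1084), so only TOV21G missed the share under 0.05. A group that mixes lines shares them with the groups it is compared with and gave 0 such genes. The 3 other splits for IGROV1 and the 4 for TOV21G each held all 3 arrays of 1 line in that group. The outcome was thus set by the makeup of the groups, and these 4 counts of splits do not decide on chance in any line. For pairs, 10 splits are too few for a share under 0.05; 1 reached the real count, and the highest other was 0.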

Other observations

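Of the tests behind the paragraphs below, those of runs of higher genes, of a swap of labels and of the ERBB2 probe set were chosen after the values were seen. Runs of neighbouring genes set single lines apart. In TOV112D, the 5 HOXC cluster genes HOXC13, HOTAIR, HOXC10, HOXC9 and HOXC8 were each higher than in every other line, as were the small proteoglycan genes EPYC, KERA, LUM and DCN (the last by a probe set ending in _x_at), the collagen genes COL3A1 and COL5A2 with their neighbours, and a run of keratin and hair keratin-associated genes. KRT20, a keratin of intestinal epithelium, was at 9.52 in TOV112D and at 2.29 to 2.54 elsewhere. In the same line TES, CAV2, CAV1 and the receptor gene MET lay side by side and were lower, with MET at 3.47 against 8.52 or above. The interferon-induced IFITM1, IFITM2 and IFITM3 were lower in TOV112D by 5.49, 6.77 and 7.26 and higher in IGROV1 by 4.04, 3.88 and 3.94. The IGROV1 differences owe much to the low TOV112D values. In IGROV1 these genes were at 10.94, 12.58 and 12.58, against 9.55, 11.33 and 11.30 in TOV21G. IFITM2 and IFITM3 were measured by probe sets ending in _x_at, open to cross-hybridisation, with nearly equal values (12.58 for both in IGROV1). S100A2, S100A4, S100A6 and S100A16 were lower in TOV112D.

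In TOV21G the metallothionein genes MT2A, MT1E, MT1F, MT1G, MT1H and MT1X were higher by 2.16 to 2.43, each measured by a probe set ending in _x_at, and without such probe sets the MT1G difference was 0.21. Of the X-linked neighbours BEX1, BEX4, BEX2 and TCEAL7, only TCEAL7 was near the floor in all other lines (10.19 in the arrays labelled SKOV3, at most 2.01 elsewhere), while the first 3 were at 11.66, 10.29 and 9.48 there against 10.39, 7.93 and 7.65 in the next line. In IGROV1, TIAM1, its antisense gene, SCAF4 and HUNK lay together and were lower, with TIAM1 at 3.41 against 5.44 to 9.46. The antisense gene was dim, at 2.83 against 3.85 to 4.57, and these 4 genes just reach the minimum for a run.

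At least 4 of 5 neighbouring bright genes set apart in the same direction made a run, and runs held 17 lower genes in TOV112D and 4 in IGROV1 (permutation p over 1000 shuffled gene orders = 0.001, the smallest possible, and 0.031), and 0 in the arrays labelled SKOV3 and 0 in TOV21G (permutation p = 1 for each). Runs held 30 higher genes in TOV112D, 16 in the arrays labelled SKOV3 and 14 in TOV21G (permutation p = 0.001 for each), and 4 in IGROV1 (permutation p = 0.0759, chance order not excluded). Tandem gene families make up many runs, and probe sets shared between similar genes could add to them: without genes measured by _x_at or _s_at probe sets, 4 of 11 remaining genes stayed in runs of lower genes in TOV112D, which decides nothing, and 0 in IGROV1, while in runs of higher genes 9 of 19 stayed in TOV112D, 4 of 11 in the arrays labelled SKOV3 and 4 of 7 in TOV21G. The rule that this test is void with under 4 remaining genes was added after its values were seen. By the prediction as first written, the 0 of 2 genes in IGROV1 would have counted for shared probe sets. With only 2 genes left, however, a run of at least 4 could hardly remain. That result therefore decides nothing, and shared probe sets stay open for the IGROV1 run. The 0 in the arrays labelled SKOV3 and in TOV21G tested nothing. No biological explanation was tested.

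ERBB2 was not raised in the arrays labelled SKOV3, although that line is known for its amplification. A swap of labels among the 4 lines would need another line with high ERBB2, but the highest of the other 3 exceeded the next by only 0.19 on the log2 scale, and a failed ERBB2 probe set would leave the co-amplified STARD3, PGAP3, MIEN1 and GRB7 raised, but their median difference was -0.50. A hypothesis is that these arrays may come from another cell line, or a subline, under the SKOV3 label: a list of further pluripotency genes shifted up there (camera p = 6e-05 across genes, and 0.0052 with an estimated correlation), with 7 of 28 members higher and 0 lower, against at most 1 higher in any other line. That list was written before its own values were seen but after those of LIN28A, NANOG, SOX2, SALL4 and TRIM71, and the shift rests on part of it, since OTX2, NR6A1 and PRDM14 were at 8.61, 10.28 and 8.91 against 2.24, 5.90 and 4.84 or less while DPPA2, ZFP42 and L1TD1 did not pass the test. The culture medium, which differs only for this group, and a loss of the amplification in culture stay open and untested. The list shift, with a median difference of 0.35, cannot tell another cell line from a subline or from an effect of the medium.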
